A study of Mus musculus with 12 samples.

How the data were processed

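RNA was measured in cerebral cortex of male C57BL/6N mice aged 9 weeks, in 4 groups of 3 libraries. Per the labels' protocols, a silicon-coated filament blocked the middle cerebral artery for 1 h, reperfusion lasted 6 h, 12 h or 24 h, and the infarcted cortex on the side of the occlusion was taken. Total RNA with an integrity number above 8 was depleted of ribosomal RNA, and stranded libraries from 100 ng were sequenced as paired reads of 50 bp. Per the submitters' processing notes, reads were aligned with TopHat2 2.0.11 and Bowtie2 2.2.2 to GRCm38 and transcripts were assembled with Cufflinks 2.2.2, with Cuffdiff, whose version is not given, used for comparisons. The strand setting of the counting is not given. Each deposited file lists FPKM (fragment values scaled to transcript length and library total) for reference transcripts and for transcripts assembled in that library, as the authors' Cufflinks run wrote them, 1 library at a time.

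Reference transcripts were matched to genes by GENCODE M21, which held 98.0% of the 110299 transcripts in the files, giving 45343 genes. Left out were 72 genes with a transcript of at least 1 FPKM on average that was absent from some library. A gene's value was the sum of FPKM over its reference transcripts divided by the library's median-of-ratios factor, and these factors ran from 0.896 in 6 h replicate 3 to 1.15 in 24 h replicate 1. No transcript above 0 had a fraction of its overlapping transcripts under 0.1, so a value of 0 may mean a fraction under that floor. Assembled transcripts held between 4.33% and 9.27% of gene FPKM per library, and between 16641 and 33945 of them were present. Genes were tested if at least 1 FPKM in at least 3 of the 12 libraries with a longest transcript of at least 300 nt, which left 12597. A gene under 1 FPKM throughout sham was tested only if stroke libraries reached that value. Counts and tests over lists of genes low in sham therefore favour a rise. The fit was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with group means, a mean-variance trend and no covariate; calls had a Benjamini-Hochberg adjusted p under 0.05. With 3 libraries against 3 the smallest exact permutation p is 0.1, so single genes rest on the fitted spread.

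The comparisons were each stroke time against sham and each pair of stroke times. Isoform use was tested with diffSplice of limma, requiring a shift of at least 10 percentage points in a transcript's mean share. Assembled transcripts in clusters without a reference transcript were merged by overlap on the same strand into loci of at least 300 nt. There were 20 gene lists and 15 marker lists, tested with camera at a preset correlation of 0.01 and again with the correlation estimated, adjusted over lists within a comparison. Lists, tests, groups and the rule for naming genes were fixed before the data were examined. The rule named the 12 protein-coding genes with the largest change each way against sham among called genes whose libraries did not overlap, 8 each way between times, 5 noncoding genes each way, 5 isoform genes per time and up to 4 called members per list. The text leads with genes called the same way when assembled transcripts were added, with at least 0.5 of their log2 fold change left. Of the 12 higher genes the rule named, 8, 7 and 7 met this at 6 h, 12 h and 24 h, and of the 12 lower genes 1, 1 and 2; where a gene did not, the next in order was taken, a choice made after the values were seen. Hspa1a and Hspa1b are near-identical copies, and Lyz2, Serpina3n, Chil3 and ribosomal protein genes have close copies or pseudogenes, so the division of reads between copies is uncertain.

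The alternatives tried were 2 other scalings, a pseudocount of 0.1, other filters, the top transcript alone, assembled transcripts added, fits on 2 groups, a replicate block, no trend, library weights, a fold minimum of 2 and the omission of each library. Genes or transcripts above 0 throughout, calls shared by both gene values, lists with assembled transcripts, and for loci the block and omissions were added after the data were seen. Overlap between times was set beside 20 simulations of unchanged groups. The gene test was tested on simulated data for the 6 h comparison. Of 100 genes given a 2-fold change 52% were recovered, and of 100 given a 4-fold change 91%. The changed genes all had a simulated mean of at least 2 FPKM, so recovery of lower genes was not measured. There were 26 false calls among 12597 genes. Beside the 52 and 91 genes recovered, these 26 were a larger share of the calls than the adjusted p threshold allows. The share of false calls was therefore not held to that threshold in this simulation. For isoforms a shift of 20 points was recovered in 19% of 100 genes and one of 40 points in 48%, with 1 false call. Values there were overall transcript means plus shuffled deviations, so transcripts at 0 throughout only 1 group were not reproduced. The 1 false call therefore does not describe calls on such transcripts, and other splits of the 6 h and sham libraries called up to 40 genes. Lists shifted by 0.5 on the log2 scale were recovered in 100% of 50. Their members were random genes moved alike, so this says little about lists whose members vary together. Median correlation of a library with its group ran from 0.908 to 0.930, and from 0.958 to 0.977 with assembled transcripts added. Tables used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Fold changes against groups listed at 0 are not reported here.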

Results

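The series measured RNA in the cerebral cortex of male mice after a transient stroke, in which the middle cerebral artery was blocked for 1 h and blood flow was then restored. Cortex was taken at 6 h, 12 h or 24 h of reperfusion, and the sham group had the neck incision without the blocking filament. Each of the 4 groups had 3 libraries, 12 in all, and the triplicates are described as independent replicate samples. The files hold 110299 reference transcripts, 651 of them absent from some library, and between 74.6% and 77.7% of those in a library were listed at 0. Between 11056 and 11807 genes per library reached 1 FPKM. Read totals per library are not given in the sources used here, so no counting interval could be set on a single value. The read coverage per FPKM of a library, relative to the lowest library, ran from 1.00 in 12 h replicate 2 to 1.54 in 24 h replicate 1. The submitters pooled the triplicates of each group in equal amounts before sequencing, and no run is recorded, so a sequencing run and a group cannot be told apart. Values are scaled FPKM as mean ± SD with n = 3, and log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes.

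**Figure D1:**
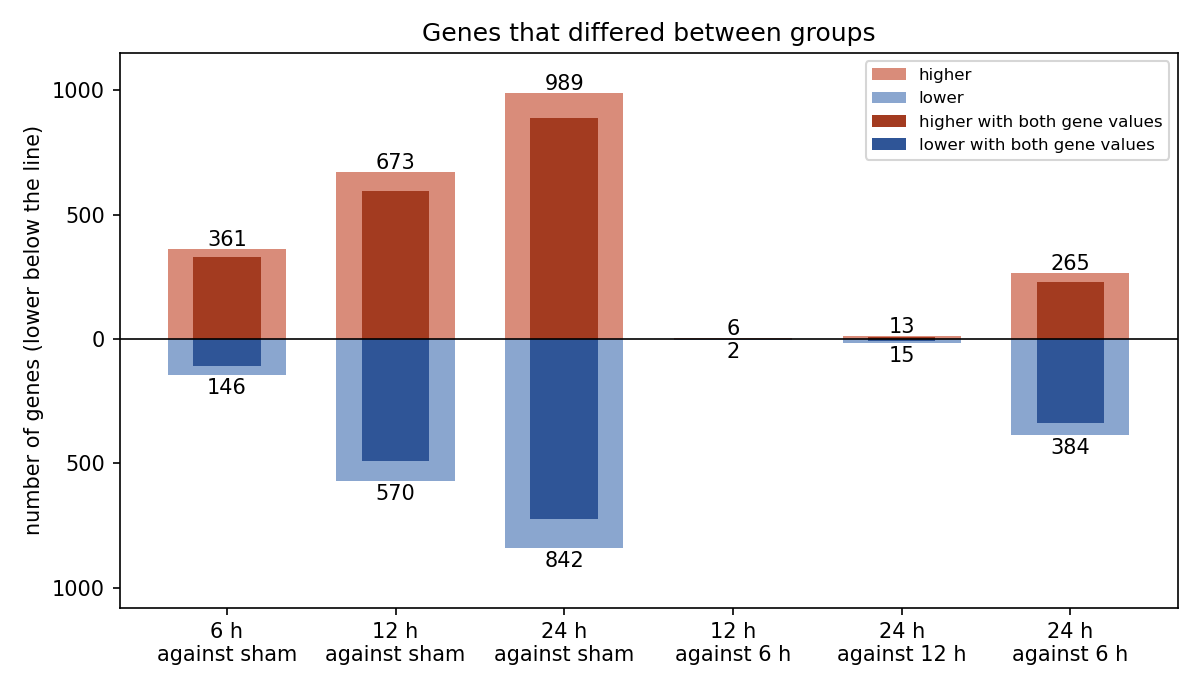
Numbers of genes higher (above the line) and lower (below the line) in each comparison of the groups, out of 12597 genes tested with limma; the inner bars count genes called the same way when assembled transcripts were added to the gene values. The counts against sham were 361 and 146 at 6 h, 673 and 570 at 12 h, and 989 and 842 at 24 h.

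The first comparison asked which transcripts differed from sham cortex at 6 h of reperfusion. Genes of the heat shock, chemokine and reactive astrocyte lists were among those higher, and neuronal genes were among a smaller set that was lower. With an estimated correlation no list met the threshold at 6 h (lowest adjusted p 0.069). Hspa1b, which encodes an inducible heat shock protein (ENSMUSG00000090877, chromosome 17, 34956436 to 34959238 in GRCm38), rose from 2.39 ± 0.231 FPKM in sham to 134 ± 40.4 (log2 fold change 5.28, SE 0.33, limma adjusted p 3.77e-05). Lcn2, a secreted iron-carrier binding protein made by neutrophils and reactive astrocytes (ENSMUSG00000026822, chromosome 2, 32384633 to 32388252), rose from 1.79 ± 0.72 to 47.2 ± 10.9 FPKM (log2 fold change 4.12, SE 0.37, limma adjusted p 0.000363). Ccl2, a chemokine that attracts monocytes, rose from 0.0572 ± 0.0391 to 12.3 ± 3.98 FPKM (log2 fold change 3.61, SE 0.29, limma adjusted p 0.000188). Gpr26, an orphan receptor of neurons (ENSMUSG00000040125, chromosome 7, 131966460 to 131994405), fell from 25.8 ± 1.44 to 11.8 ± 0.96 FPKM (log2 fold change -1.07, SE 0.17, limma adjusted p 0.0071).

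Of the 18 measured heat shock protein genes, 6 rose, or 8 adjusted over the list alone (camera adjusted p 6.28e-07, adjusted p = 0.237 with an estimated correlation). Beside Hspa1b (5.28) and its near-identical neighbour Hspa1a (5.17), these included the small heat shock protein gene Hspb1 (2.96). Among the 31 measured immediate early genes, which answer within minutes to activity or injury, 10 rose, or 14 adjusted over the list alone (camera adjusted p 2.32e-08, adjusted p = 0.169 with an estimated correlation). They included the stress-induced transcription factor genes Atf3 (3.06) and Maff (3.03) and the DNA damage response gene Gadd45b (1.99). The chemokine and cytokine list had 10 of 24 members higher, or 14 adjusted over the list alone (camera adjusted p 4.13e-10, adjusted p = 0.0926 with an estimated correlation), with Ccl2 and the macrophage inflammatory protein genes Ccl3 (4.55) and Ccl4 (4.32) as examples. The reactive astrocyte list had 14 of 33 members higher and none lower, or 20 adjusted over the list alone (camera adjusted p 4.07e-14, adjusted p = 0.069 with an estimated correlation). Examples were Lcn2, the metalloproteinase inhibitor gene Timp1 (3.65) and the cytokine signalling inhibitor gene Socs3 (2.81). In the extracellular matrix and protease list 10 of 25 members rose, or 13 adjusted over the list alone (camera adjusted p 3.14e-12, adjusted p = 0.0926 with an estimated correlation), among them Timp1 and the urokinase receptor gene Plaur (2.75). The oxidative stress list of NRF2 targets had 7 of 21 members higher, or 10 adjusted over the list alone (camera adjusted p 7.37e-07, adjusted p = 0.103 with an estimated correlation), among them the metallothionein gene Mt2 (2.37) and the heme oxygenase gene Hmox1 (2.37).

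Smaller groups also moved at 6 h. Neutrophil markers had 4 of 6 measured members higher (camera adjusted p 1.01e-05, adjusted p = 0.0926 with an estimated correlation), with S100a8 (2.16), which encodes a subunit of calprotectin, beside Lcn2. The endothelial marker list had 5 of 18 members higher (camera adjusted p 0.0231, adjusted p = 0.491 with an estimated correlation), including the vascular cadherin gene Cdh5 (1.51) and the glucose transporter gene Slc2a1 (1.22); its call was lost with assembled transcripts added. The adhesion gene Icam1 (2.33) and the TNF receptor family gene Tnfrsf12a (2.07) rose as well. Endothelial adhesion genes had 2 of 8 higher (camera adjusted p 0.00967, adjusted p = 0.169 with an estimated correlation). The p53 and apoptosis list had 3 of 19 higher (camera adjusted p 0.000522, adjusted p = 0.13 with an estimated correlation), and the hypoxia and glycolysis list 4 of 24 (camera adjusted p 0.00751, adjusted p = 0.13 with an estimated correlation). The bacterial product receptor gene Cd14 (3.30) was the single member higher of 8 inflammasome genes (camera adjusted p 0.00328, adjusted p = 0.169 with an estimated correlation). Cholesterol synthesis had 2 of 20 genes higher, or 10 adjusted over the list alone (camera adjusted p 0.000333, adjusted p = 0.279 with an estimated correlation). Ribosomal protein genes had 3 of 40 higher, or 15 adjusted over the list alone (camera adjusted p 4.94e-09, adjusted p = 0.169 with an estimated correlation). Monocyte and macrophage markers had 2 of 12 higher (camera adjusted p 0.000647, adjusted p = 0.0926 with an estimated correlation) and oligodendrocyte markers 1 of 15 (camera adjusted p 0.00754, adjusted p = 0.491 with an estimated correlation). Astrocyte markers shifted up as a list with no single member called (camera adjusted p 6.76e-05, adjusted p = 0.253 with an estimated correlation).

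Neuronal genes were among those lower at 6 h. Of 34 glutamate and GABA receptor genes 2 fell (camera adjusted p 0.000333, adjusted p = 0.13 with an estimated correlation). Of 42 voltage-gated ion channel genes 4 fell and 1 rose (camera adjusted p 0.0101, adjusted p = 0.0926 with an estimated correlation). Of 20 neuron markers 2 fell (camera adjusted p 0.0231, adjusted p = 0.237 with an estimated correlation), with a list median of -0.14 but a mean of 0.05. No member of the synaptic list was called (camera adjusted p 0.034, adjusted p = 0.56 with an estimated correlation). Microglia markers had 2 of 16 lower, and the list was not called (camera adjusted p 0.0665, adjusted p = 0.612 with an estimated correlation); with assembled transcripts added 5 of 18 were lower and it was called (camera adjusted p 0.0232, adjusted p = 0.668 with an estimated correlation). The microglial receptor gene Gpr34 (-1.19), the stress gene Ddit4l (-1.07) and the cortical neuron transcription factor gene Neurod6 (-1.06) fell. Their calls lay near the threshold, and each missed it without sham replicate 1 or 6 h replicate 2. Gpr34 and Ddit4l also missed it without sham replicate 2, and Neurod6 without sham replicate 3 or 6 h replicate 3. The log2 fold changes stayed of similar size over the omissions: -1.246 to -1.131 for Gpr34, -1.195 to -0.916 for Ddit4l and -1.165 to -0.951 for Neurod6. Over all single-library omissions the adjusted p values of Gpr34, Ddit4l and Neurod6 reached 0.059, 0.0581 and 0.101, respectively. Gpr34 also missed the threshold with a pseudocount of 0.1 and with its top transcript alone, and Neurod6 with no filter. Gpr26 was called whichever library was omitted.

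At 6 h 361 genes were higher and 146 lower of 12597 tested. All 507 had 6 h libraries that did not overlap the sham libraries, as 31.5% of all genes tested did; chance gives 10% for 3 against 3. With assembled transcripts added to the gene values the counts were 911 and 730 of 13394, and 329 and 110 were called the same way with both gene values. Of the list counts given above, these moved by more than 1.5 times with assembled transcripts added: 24 of 35 reactive astrocyte genes, 5 of 9 endothelial adhesion genes, 5 of 20 p53 list genes, 7 of 24 hypoxia and glycolysis genes, 3 of 10 inflammasome genes, 7 of 20 cholesterol synthesis genes, 7 of 40 ribosomal protein genes and 4 of 15 oligodendrocyte markers were higher; 9 of 36 receptor genes, 13 of 42 ion channel genes and 4 of 20 neuron markers were lower. Of the ion channel calls 4 lower and 0 higher held with both gene values. Without further scaling of the deposited values the higher share of calls went from 71.2% to 46.9% (245 higher, 277 lower), and with assembled transcripts added it was 55.5%. For the higher genes, omitting any of sham replicates 1, 2 and 3 or 6 h replicates 1, 2 and 3 moved the count to between 167 and 236. For the lower genes, omitting any of sham replicates 1, 2 and 3, 6 h replicates 1, 2 and 3, 12 h replicates 1 and 3 or 24 h replicate 2 moved the count to between 33 and 268.

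The comparison of 12 h with sham covered the middle of the time course. Genes of the chemokine, reactive astrocyte and oxidative stress lists were among those higher, and genes of ion channels, neurotransmitter receptors and cortical neurons were among those lower. With an estimated correlation the reactive astrocyte, matrix and protease, ion channel and monocyte lists met the threshold and the others did not. Ccl2 stood at 25.6 ± 1.92 FPKM against 0.0572 ± 0.0391 in sham (log2 fold change 4.65, SE 0.29, limma adjusted p 2.11e-05). Spp1, which encodes the secreted matrix protein osteopontin, rose from 3.3 ± 1.13 to 46.8 ± 9.83 FPKM (log2 fold change 3.48, SE 0.27, limma adjusted p 6.8e-05). Lamp5, a membrane protein gene of cortical neurons (ENSMUSG00000027270, chromosome 2, 136052239 to 136069917 in GRCm38), fell from 64.1 ± 1.58 to 21.2 ± 1.48 FPKM (log2 fold change -1.55, SE 0.25, limma adjusted p 0.00429). Kcnq3, which encodes a subunit of the potassium channel behind the M-current (ENSMUSG00000056258, chromosome 15, 65986387 to 66286642), fell from 17.7 ± 1.92 to 6.25 ± 0.635 FPKM (log2 fold change -1.36, SE 0.14, limma adjusted p 0.000465).

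Of 24 measured chemokine and cytokine genes 15 rose and 2 fell (camera adjusted p 2.03e-13, adjusted p = 0.0541 with an estimated correlation), and adjusted over the list alone 22 rose. The neutrophil chemokine gene Cxcl1 (3.99) was among them. Reactive astrocyte genes had 20 of 33 higher, or 24 adjusted over the list alone (camera adjusted p 6.75e-17, adjusted p = 0.0199 with an estimated correlation), with Timp1 (4.65), Lcn2 (4.51) and Socs3 (3.27) among them. Extracellular matrix and protease genes had 14 of 25 higher, or 15 adjusted over the list alone (camera adjusted p 9.17e-14, adjusted p = 0.0382 with an estimated correlation). Mmp3, a matrix metalloproteinase gene that was listed at 0 in all 3 sham libraries, held 4.5, 5.95 and 6.37 FPKM at 12 h (limma adjusted p 9.2e-06). The heat shock genes had 8 of 18 members higher (camera adjusted p 2.19e-05, adjusted p = 0.361 with an estimated correlation), including Hspa1b (4.91). NRF2 targets had 8 of 21 higher (camera adjusted p 3.24e-07, adjusted p = 0.0833 with an estimated correlation), with Hmox1 (3.31) and Mt2 (3.2). Immediate early genes had 9 of 31 higher and 2 lower (camera adjusted p 0.00532, adjusted p = 0.493 with an estimated correlation). The inflammasome list had 3 of 8 higher (camera adjusted p 0.00182, adjusted p = 0.167 with an estimated correlation), Cd14 (3.94) among them. The p53 list had 5 of 19 higher and 1 lower (camera adjusted p 0.000139, adjusted p = 0.097 with an estimated correlation).

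Some markers of white blood cells were higher too. Neutrophil markers had 4 of 6 measured members higher (camera adjusted p 1.18e-05, adjusted p = 0.0833 with an estimated correlation). Monocyte and macrophage markers had 4 of 12 higher (camera adjusted p 2.09e-05, adjusted p = 0.0323 with an estimated correlation), including the scavenger receptor gene Msr1 (1.65) and the lysosomal membrane gene Cd68 (1.63). Endothelial markers had 4 of 18 higher and 1 lower (camera adjusted p 0.0115, adjusted p = 0.47 with an estimated correlation), and that list call was lost with assembled transcripts added. Ribosomal protein genes had 7 of 40 higher, or 18 adjusted over the list alone (camera adjusted p 1.89e-07, adjusted p = 0.241 with an estimated correlation). Cholesterol synthesis had 4 of 20 higher (camera adjusted p 0.00459, adjusted p = 0.47 with an estimated correlation).

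Channel, receptor and synaptic genes were among the 570 lower at 12 h. Voltage-gated ion channel genes had 13 of 42 members lower and 1 higher, or 15 lower adjusted over the list alone (camera adjusted p 2.81e-07, adjusted p = 0.00806 with an estimated correlation). The channel-associated gene Kcnip2 (-1.44), outside that list, fell with Kcnq3. Glutamate and GABA receptor genes had 10 of 34 lower, or 14 adjusted over the list alone (camera adjusted p 2.15e-05, adjusted p = 0.0833 with an estimated correlation), among them the GABA-A receptor subunit gene Gabrd (-1.04). Synaptic genes had 6 of 30 lower, or 15 adjusted over the list alone (camera adjusted p 1.89e-07, adjusted p = 0.164 with an estimated correlation), with the presynaptic scaffold gene Pclo (-1.23). Neuron markers had 9 of 20 lower (camera adjusted p 0.000825, adjusted p = 0.097 with an estimated correlation), with a median of -0.43 but a mean of 0.05; the layer-specific transcription factor gene Rorb (-1.30) was one of them. Netrin-G1, an axon guidance molecule, is encoded by Ntng1 (-1.64), which fell, as did the microglial receptor gene Gpr34 (-1.57). Microglia markers had 3 of 16 lower, and the list was not called (camera adjusted p 0.0524, adjusted p = 0.609 with an estimated correlation); with assembled transcripts added 7 of 18 were lower and it was called (camera adjusted p 0.0196, adjusted p = 0.672 with an estimated correlation). P2ry12, the purine receptor gene of resting microglia, held 8.24, 7.16 and 7.8 FPKM in sham and was listed at 0 in all 3 libraries at 12 h (limma adjusted p 0.00426).

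At 12 h 673 genes were higher and 570 lower. All 1243 had libraries that did not overlap those of sham, as 35.9% of genes tested did against a chance share of 10%. With assembled transcripts added the counts were 1562 and 1624, and 596 and 492 were called with both gene values. Of the list counts given above, these moved by more than 1.5 times with assembled transcripts added: 5 of 10 inflammasome genes, 10 of 20 p53 list genes, 17 of 40 ribosomal protein genes, 7 of 20 cholesterol synthesis genes and 0 of 42 ion channel genes were higher; 4 of 32 immediate early genes, 2 of 18 endothelial markers, 24 of 42 ion channel genes and 14 of 30 synaptic genes were lower. With the deposited values not scaled further the higher share went from 54.1% to 64.5% (683 higher, 376 lower). For the higher genes, omitting any of sham replicates 1 and 2 or 12 h replicates 1 and 2 moved the count to between 388 and 442. For the lower genes, omitting any of sham replicates 1, 2 and 3 or 12 h replicates 1, 2 and 3 moved the count to between 243 and 370.

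The comparison of 24 h with sham covered the latest time. Osteopontin, heme oxygenase, chemokine and macrophage genes were among those higher, as were ribosomal protein genes by smaller folds, and synaptic, receptor and channel genes were among those lower. Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050 in GRCm38) rose from 3.3 ± 1.13 FPKM in sham to 117 ± 30.1 (log2 fold change 4.77, SE 0.27, limma adjusted p 5.72e-06). Hmox1, whose product breaks down heme (ENSMUSG00000005413, chromosome 8, 75093621 to 75100589), rose from 1.47 ± 0.18 to 59.9 ± 22.5 FPKM (log2 fold change 4.56, SE 0.32, limma adjusted p 2.94e-05). Lyz2, the lysozyme gene of macrophages and neutrophils, rose from 3.91 ± 2.01 to 28.5 ± 11.5 FPKM (log2 fold change 2.60, SE 0.33, limma adjusted p 0.000996). Stx1a, a gene of the synaptic vesicle fusion machinery (ENSMUSG00000007207, chromosome 5, 135023482 to 135051100), fell from 102 ± 3.54 to 48.2 ± 11.5 FPKM (log2 fold change -1.1, SE 0.15, limma adjusted p 0.00141).

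**Figure D2:**
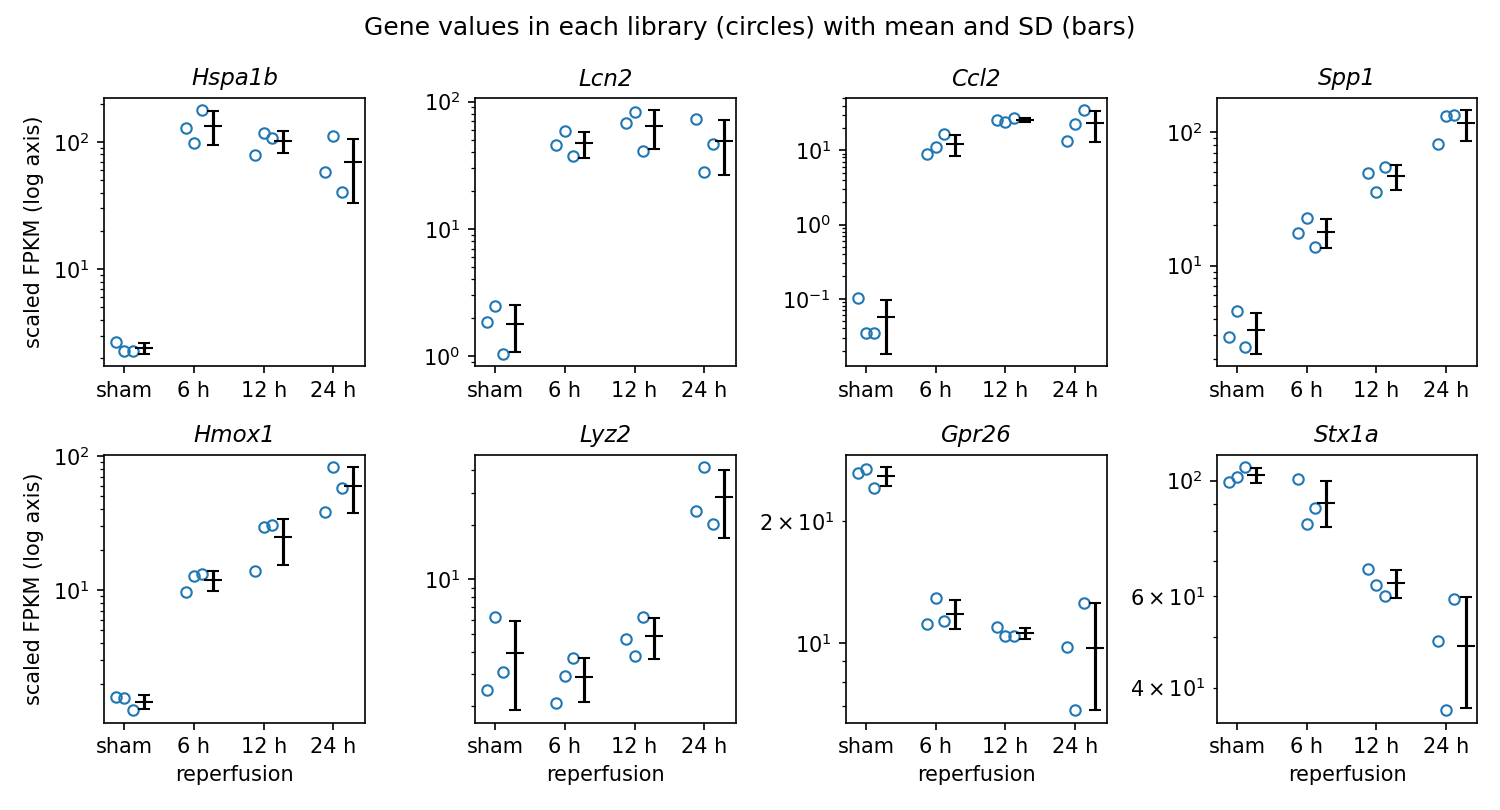
Scaled FPKM (log axis) of 8 genes in each of the 12 libraries (circles), by group, with the mean and SD of 3 libraries (bars). Spp1 and Hmox1 went from 3.3 ± 1.13 and 1.47 ± 0.18 FPKM in sham to 117 ± 30.1 and 59.9 ± 22.5 at 24 h, and Stx1a from 102 ± 3.54 to 48.2 ± 11.5.

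Chemokine and cytokine genes had 17 of 24 members higher and 2 lower, or 21 and 2 adjusted over the list alone (camera adjusted p 2.83e-13, adjusted p = 0.0355 with an estimated correlation), with Ccl2 (4.44) and Ccl12 (4.17). Reactive astrocyte genes had 20 of 33 higher, or 24 adjusted over the list alone (camera adjusted p 2.09e-18, adjusted p = 0.0101 with an estimated correlation), with the acute-phase gene Serpina3n (3.88), the pentraxin gene Ptx3 (3.51), Lcn2 (4.09) and Timp1 (4.04). NRF2 targets had 12 of 21 higher, or 13 adjusted over the list alone (camera adjusted p 2.66e-09, adjusted p = 0.0355 with an estimated correlation). Extracellular matrix and protease genes had 12 of 25 higher, or 17 adjusted over the list alone (camera adjusted p 4.33e-12, adjusted p = 0.0355 with an estimated correlation). Heat shock genes had 8 of 18 higher (camera adjusted p 1.64e-06, adjusted p = 0.26 with an estimated correlation), with Hspa1b (4.26) and the mitochondrial chaperone gene Hspe1 (1.54). Unfolded protein and integrated stress response genes had 8 of 20 higher and 1 lower (camera adjusted p 0.00095, adjusted p = 0.346 with an estimated correlation), among them the cystine transporter gene Slc7a11 (1.84). The p53 list had 7 of 19 higher and 1 lower (camera adjusted p 5.03e-06, adjusted p = 0.0384 with an estimated correlation), including the cell cycle inhibitor gene Cdkn1a (2.13). In the inflammasome list 5 of 8 were higher (camera adjusted p 6.17e-06, adjusted p = 0.0391 with an estimated correlation), including Cd14 (4.44) and the receptor gene Tlr2 (2.15). Immediate early genes had 9 of 31 higher and 1 lower (camera adjusted p 0.00105, adjusted p = 0.371 with an estimated correlation). Endothelial adhesion genes had 5 of 8 higher and 1 lower (camera adjusted p 0.00413, adjusted p = 0.127 with an estimated correlation).

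Measured white blood cell markers were higher as a group at 24 h. Markers under the minimum were not tested, and one near 0 in sham reached it only through stroke libraries. The counts and list tests of these markers therefore favour a rise. Neutrophil markers had 5 of 6 measured members higher, or 6 adjusted over the list alone (camera adjusted p 2.97e-07, adjusted p = 0.0355 with an estimated correlation), with the calprotectin genes S100a8 (3.66) and S100a9 (3.25). Monocyte and macrophage markers had 9 of 12 higher, or 11 adjusted over the list alone (camera adjusted p 4.49e-11, adjusted p = 0.00363 with an estimated correlation), with Msr1 (3.15), Lyz2 (2.60) and the chitinase-like gene Chil3 (2.59). Saa3, a serum amyloid gene listed at 0 in all 3 sham libraries, held 31.2, 23 and 6.71 FPKM (limma adjusted p 0.000423). None of the 17 lymphocyte markers reached the minimum for testing, so that list has no result. Microglia markers went both ways, 2 higher and 4 lower of 16 (camera adjusted p 0.552, adjusted p = 0.843 with an estimated correlation): the signalling adaptor gene Tyrobp (1.58) rose, Gpr34 (-1.47) fell, and P2ry12 was listed at 0 in all 3 libraries (limma adjusted p 0.00314). Red cell markers had 0 of 7 higher and 1 lower (camera adjusted p 0.664, adjusted p = 0.843 with an estimated correlation).

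Synaptic genes had 19 of 30 members lower and none higher at 24 h, or 26 adjusted over the list alone (camera adjusted p 5.16e-15, adjusted p = 0.0355 with an estimated correlation), with a median log2 fold change of -0.72. Examples were Pclo (-1.18) and Stx1a. Receptor genes had 12 of 34 lower, or 16 adjusted over the list alone (camera adjusted p 1.38e-08, adjusted p = 0.0355 with an estimated correlation), including Gabrd (-0.96). Ion channel genes had 14 of 42 lower, or 23 adjusted over the list alone (camera adjusted p 2.03e-08, adjusted p = 0.00363 with an estimated correlation), including Kcnq3 (-0.97). Neuron markers had 10 of 20 lower (camera adjusted p 1.15e-05, adjusted p = 0.0355 with an estimated correlation), among them the calcium/calmodulin kinase gene Camk2a (-0.96) and the neuronal tubulin gene Tubb3 (-0.91). Interneuron markers had 3 of 14 lower (camera adjusted p 0.0133, adjusted p = 0.346 with an estimated correlation). Outside the lists, the kinase gene Camkk2 (-2.09), the small GTPase gene Diras2 (-1.90), the vesicle priming gene Unc13a (-1.41), the sodium/calcium exchanger gene Slc8a2 (-1.33) and Gpr26 (-1.36) fell. Ribosomal protein genes moved the other way, with 31 of 40 higher and none lower, or 34 adjusted over the list alone (camera adjusted p 2.78e-18, adjusted p = 0.0391 with an estimated correlation), and a median log2 fold change of 0.48. Astrocyte markers had 0 of 15 higher and 1 lower (camera adjusted p 0.0827, adjusted p = 0.669 with an estimated correlation). Endothelial markers had 5 higher and 1 lower of 18 (camera adjusted p 0.0185, adjusted p = 0.441 with an estimated correlation).

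Among the remaining lists at 24 h, the interferon response had 2 higher and 0 lower of 21 (camera adjusted p 0.000794, adjusted p = 0.364 with an estimated correlation); at 6 h it had 1 higher and 0 lower of 21 (camera adjusted p 0.876) with a median of 0.06, a mean of -0.03 and a test pointing down, and the sign of that median flipped under both other scalings. Camera called no other list of this group: hypoxia and glycolysis had 5 higher and 0 lower of 24 (adjusted p 0.751), cholesterol synthesis 0 higher and 1 lower of 20 (0.298), cell cycle 2 higher and 0 lower of 10 (0.0771), circadian clock 1 higher and 2 lower of 19 (0.736) and oxidative phosphorylation 0 higher and 2 lower of 31 (0.0827). Oligodendrocyte markers had 1 higher and 0 lower of 15 (0.552), their precursors 1 higher and 2 lower of 10 (0.628), pericyte and smooth muscle markers 0 higher and 2 lower of 10 (0.306) and meninges and fibroblast markers 2 higher and 0 lower of 12 (0.734). Choroid plexus and ependyma markers had 0 higher and 0 lower of 2 (0.727), striatum markers 0 higher and 3 lower of 8 (0.111), and hippocampus and thalamus markers 1 higher and 0 lower of 8 (0.664). With assembled transcripts added the cell cycle list was called (0.0453). The sign of the list median flipped with the deposited values not scaled further for hypoxia and glycolysis, for microglia and for oxidative phosphorylation. In the hypoxia, clock and meninges lists the median, mean and test did not share a sign: the medians were -0.04, 0.06 and -0.36, the means 0.15, 0.04 and 0.11, and the tests pointed up, down and up.

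**Figure D3:**
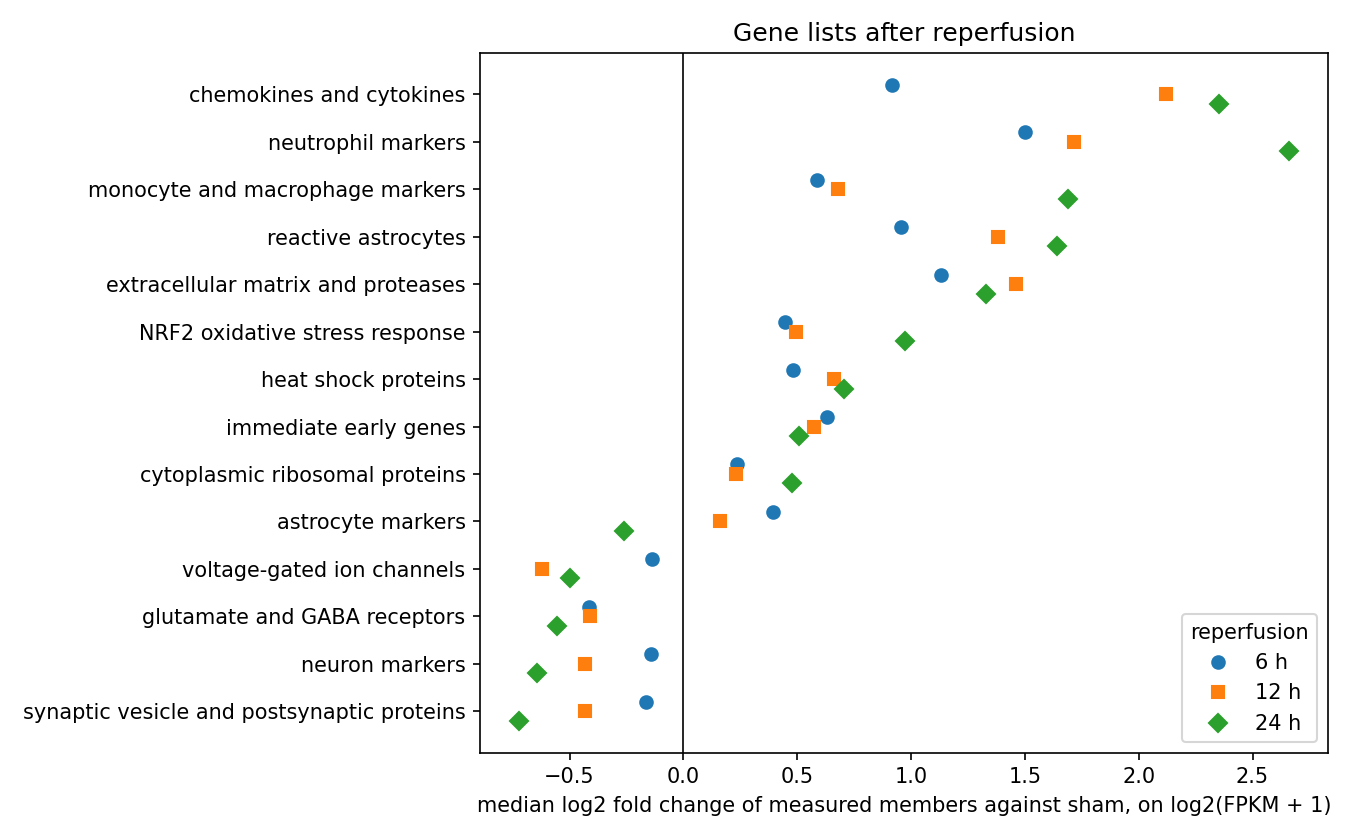
Median log2 fold change against sham of the measured members of 14 lists at 6 h, 12 h and 24 h of reperfusion (symbols), on the log2(FPKM + 1) scale. Neutrophil markers reached 2.66 and chemokines and cytokines 2.35 at 24 h, and the synaptic list -0.72.

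At 24 h 989 genes were higher and 842 lower. Of these 1831 genes, 1828 had 24 h libraries that did not overlap the sham libraries, as 33.5% of genes tested did against a chance share of 10%. Assembled transcripts raised the counts to 1896 and 1885, with 888 and 722 called with both gene values. Of the list counts given above, these moved by more than 1.5 times with assembled transcripts added: 12 of 20 p53 list genes, 8 of 10 inflammasome genes and 9 of 23 interferon response genes were higher; 2 of 20 unfolded protein response genes, 2 of 20 p53 list genes, 4 of 32 immediate early genes, 25 of 36 receptor genes, 30 of 42 ion channel genes and 5 of 14 interneuron markers were lower. Deposited values with no further scaling shifted the median of all genes by 0.10 and the higher share from 54.0% to 73.1% (1260 higher, 463 lower). A fit on the 6 libraries of the 2 groups alone called 462 and 280. For the higher genes, omitting any of sham replicate 1 or 24 h replicate 2 moved the count to between 644 and 654. For the lower genes, omitting any of sham replicates 1, 2 and 3 or 24 h replicate 2 moved the count to between 478 and 535.

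Annotated noncoding genes were named by the same rule. Gm12840, a predicted long noncoding gene (ENSMUSG00000086320, chromosome 4, 117700188 to 117700923 in GRCm38), rose at 6 h from 1.82 ± 1.8 to 98.9 ± 26.5 FPKM (log2 fold change 5.37, SE 0.65, limma adjusted p 0.00177). Gm26809, another predicted gene, rose at 6 h (4.15), as did Gm27010 (2.17), and the small nucleolar RNA host gene Snhg15 rose at 24 h (2.29). The 24 h call of Gm12840 (3.63) was lost in the fit on the 6 libraries of those groups alone. On the lower side the 1 noncoding gene named by the rule at 6 h (Tmem147os) did not hold with both gene values, and of 5 named at each later time 1 held, Gm12371 (-1.11) at 12 h and Gm21955 (-0.89) at 24 h. Gm12371 lost its call without sham replicate 1 or 2 or 12 h replicate 2 or 3 (highest adjusted p 0.0641).

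The contrasts between reperfusion times asked which of these differences changed with time. From 6 h to 12 h 6 genes were higher and 2 lower. Mmp3, listed at 0 in sham, went from 0.379 ± 0.164 to 5.6 ± 0.984 FPKM (log2 fold change 2.26, SE 0.15, limma adjusted p 0.000111). Ptx3, which encodes a pattern-recognition protein of innate immunity, rose from 0.59 ± 0.0875 to 4.66 ± 1.42 FPKM (log2 fold change 1.80, SE 0.18, limma adjusted p 0.00363), and the presynaptic gene Rims3 fell from 37 ± 0.738 to 22.7 ± 0.661 (log2 fold change -0.68, SE 0.08, limma adjusted p 0.0113). Ion channel genes shifted lower as a list, with a median of -0.32 and no single member called (camera adjusted p 2.21e-06, adjusted p = 0.01 with an estimated correlation). Rims3 lost its call without 6 h replicate 3 or 12 h replicate 2 (highest adjusted p 0.0736), with the deposited values not scaled further and with a fold minimum of 2. The deposited values shifted the median of all genes by 0.14 here. Ptx3 lost its call in the fit on the 6 libraries of the 2 groups alone. Separately, omitting any of 6 h replicate 1, 12 h replicates 1 and 3 or 24 h replicates 1 and 2 moved the count of 8 to between 13 and 15.

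From 12 h to 24 h 13 genes were higher and 15 lower. Lyz2 rose from 4.9 ± 1.24 to 28.5 ± 11.5 FPKM (log2 fold change 2.27, SE 0.33, limma adjusted p 0.0356), Chil3 from 0.387 ± 0.253 to 5.8 ± 2.04 (log2 fold change 2.27, SE 0.24, limma adjusted p 0.00682) and Msr1 from 2.43 ± 0.419 to 8.93 ± 2.91 (log2 fold change 1.5, SE 0.21, limma adjusted p 0.0341). Monocyte and macrophage markers rose as a list, 4 of 12 members (camera adjusted p 2.66e-08, adjusted p = 0.0168 with an estimated correlation). The kinase gene Camkk1 fell from 49.4 ± 4.48 to 20.4 ± 2.23 FPKM (log2 fold change -1.24, SE 0.19, limma adjusted p 0.0435), the neuronal pentraxin gene Nptx1 had a log2 fold change of -0.69, and the GABA-B receptor gene Gabbr2 one of -0.54. These calls lay near the threshold. Chil3 kept its call when any library was omitted but lost it in the fit on the 6 libraries of the 2 groups alone and with a pseudocount of 0.1. Lyz2, Msr1, Nptx1 and Gabbr2 lost it in that fit too, and these and Camkk1 with the deposited values not scaled further, with a replicate block and with library weights. Lyz2, Msr1, Camkk1, Nptx1 and Gabbr2 each lost it without sham replicate 1 or 3, 6 h replicate 2 or 3, 12 h replicate 1 or 2, or 24 h replicate 1 or 2. Lyz2, Msr1 and Camkk1 lost it without 12 h replicate 3 too, and Nptx1 and Gabbr2 without sham replicate 2 too (highest adjusted p for Lyz2, Msr1, Camkk1, Nptx1 and Gabbr2 0.117, 0.111, 0.133, 0.111 and 0.117). Separately, omitting any of sham replicates 1, 2 and 3, 6 h replicates 2 and 3, 12 h replicates 1 and 2 or 24 h replicates 2 and 3 moved the count of 28 to between 7 and 177.

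From 6 h to 24 h 265 genes were higher and 384 lower. Ptx3 rose from 0.59 ± 0.0875 to 11.4 ± 1.85 FPKM (log2 fold change 2.95, SE 0.18, limma adjusted p 4.22e-05), and Spp1 (2.62), Lyz2 (2.87), Ccl12 (2.76), Mmp3 (2.93), Serpina3n (3.01) and Hmox1 (2.18) rose as well. Carbonic anhydrase gene Car12 fell from 3.18 ± 1.2 to 0.337 ± 0.0699 FPKM (log2 fold change -1.6, SE 0.24, limma adjusted p 0.00795), and Camk2a (-0.99) and Stx1a (-0.92) fell. Synaptic genes had 12 of 30 lower (camera adjusted p 7.1e-14, adjusted p = 0.122 with an estimated correlation). Ion channel genes had 4 of 42 lower (camera adjusted p 8e-06, adjusted p = 0.00912 with an estimated correlation) and astrocyte markers 5 of 15 (camera adjusted p 7.73e-08, adjusted p = 0.164 with an estimated correlation). Monocyte and macrophage markers had 6 of 12 higher (camera adjusted p 6.3e-09, adjusted p = 0.00912 with an estimated correlation). Deposited values with no further scaling shifted the median of all genes by 0.21 and turned the split to 1157 higher and 188 lower. Serpina3n, Hmox1, Car12, Camk2a and Stx1a missed the threshold in the fit on the 6 libraries of these groups alone, which gave 40 calls, and omitting any of 6 h replicates 1, 2 and 3 or 24 h replicates 2 and 3 moved the count of 649 to between 209 and 1001.

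Across the 3 comparisons with sham, 241 genes were higher and 68 lower at every time, against 1.51 and 0.442 for independent lists of these sizes. In 20 simulations of unchanged groups, built from overall gene means and library deviations shuffled over the 12 libraries, the means were 0 and 0. Unchanged groups leave few calls to overlap, so those means were near 0 in advance and do not measure what the shared sham libraries add. Shared calls between 6 h and 12 h were 297 higher and 99 lower (19.3 and 6.61 for independent lists), between 6 h and 24 h 261 and 74 (28.3 and 9.76), and between 12 h and 24 h 459 and 370 (52.8 and 38.1); in the last pair 1 gene was called in opposite directions. Across genes, which are not independent replicates, fold changes of 12 h and 24 h had a correlation of 0.715 (0.509 simulated) and a covariance of 0.259 (0.0864 simulated, a difference of 0.173). For 6 h and 12 h the correlation was 0.712 (0.484 simulated) and the covariance 0.222 (0.0836 simulated), and for 6 h and 24 h the correlation was 0.615 (0.539 simulated), a smaller excess, and the covariance 0.199 (0.0919 simulated). The 3 sham libraries were too few to split, so part of the excess may come from the shared controls. For the 309 genes called alike at all times, omitting any of sham replicates 1, 2 and 3 or 6 h replicates 2 and 3 moved the count to between 158 and 187.

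Relative isoform use was compared in 3585 genes with 8444 transcripts. At 6 h 50 genes shifted a transcript's share by at least 10 percentage points, at 12 h 81 and at 24 h 72, but in 48, 77 and 67 of these a transcript was listed at 0 in some library. In the other 2, 4 and 5 every transcript was above 0 throughout. A separate test on the 668 genes of that kind alone called 4, 20 and 16. Tsc22d3, a glucocorticoid-induced gene, had transcript ENSMUST00000112995 at 46.4 ± 1.44% of its gene in sham and 19.5 ± 1.71% at 6 h (limma adjusted p 0.00287). Csnk1d, a casein kinase gene, had ENSMUST00000070575 at 75.7 ± 1.64% and 53.8 ± 4.43% (limma adjusted p 0.0273). At 12 h the share of ENSMUST00000106497 of the adaptor gene Grb2 was 18.9 ± 4.31% against 49.5 ± 11.7% in sham (limma adjusted p 0.0191), and at 24 h that of ENSMUST00000154078 of the kinase anchoring gene Akap5 was 34.5 ± 18.3% against 77.2 ± 7.71% (limma adjusted p 0.025). These genes were chosen after their values were seen, because the 15 named by the fixed rule (among them Shroom2, Dgki, Hdac1, Coa7 and Anxa7) all included a transcript listed at 0. At 6 h omitting sham replicate 1 moved the count of 50 to 30, and at 24 h omitting sham replicate 2 moved the count of 72 to 36.

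Assembled transcripts outside the reference were merged into loci, of which 3356 were tested, 287 with more than 1 exon. A library in which a locus was not assembled has no value in the files and was given 0. The strand setting of the assembly is not given, and the strand of a locus with 1 exon, and so its antisense position, rests on it. At 6 h 613 loci were higher and 18 lower, at 12 h 363 and 17, and at 24 h 171 and 1, nearly all with 1 exon: 608, 353 and 170 of the higher ones. The median log2 fold change over the loci was itself 0.40 at 6 h. A locus not assembled in sham was tested only through stroke libraries, and 574 of the 613 were of that kind. Sham replicate 3 had the fewest assembled transcripts in clusters without a reference transcript (8732). Sham replicates 1 and 2 had 17167 and 12012, and 6 h replicates 1, 2 and 3 had 13896, 18565 and 13814. The counts alone do not separate a rise of single loci from an overall shift. A locus on the minus strand of chromosome 8 from 70744015 to 70744696 in GRCm38, antisense to Pde4c, was not assembled in any sham library and held 65.3, 58.8 and 77 FPKM at 6 h, 33.5, 81.6 and 73.2 at 12 h, and 17.6, 6.58 and 17 at 24 h (limma adjusted p 1.04e-05 at 6 h). A locus on chromosome 5 from 137334207 to 137334586, also not assembled in sham, held 65.2, 53.6 and 68.6 FPKM at 6 h (limma adjusted p 6.55e-06). The locus with 2 exons on chromosome 9 from 40820767 to 40830115, whose start lies 10680 nt past the annotated end of the heat shock gene Hspa8, held 5.24, 7.46 and 4.35 FPKM at 6 h and was not assembled in sham (limma adjusted p 0.000186). The highest 6 h mean, on chromosome 11 from 120344881 to 120345207, rested on 6 h replicate 2, with 3 library values of 13.9, 2762 and 17.7 FPKM. Between 6 h and 24 h 28 loci were higher and 259 lower. Of the counts against sham, omitting any of sham replicate 1 or 6 h replicates 1 and 3 moved the 18 to between 8 and 9, omitting any of sham replicates 1, 2 and 3 moved the 363 to between 226 and 234. For 12 h lower loci, omitting any of sham replicates 1, 2 and 3 or 12 h replicate 2 moved the 17 to between 5 and 9, and for 24 h higher loci, omitting any of sham replicates 1, 2 and 3 moved the 171 to between 96 and 106. For 24 h lower loci, omitting any of sham replicates 1, 2 and 3, 6 h replicates 1, 2 and 3, 12 h replicates 1 and 2 or 24 h replicate 3 moved the count of 1 to between 0 and 3.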

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

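Differences between the stroke times were tested directly, and those called in the fit on all 12 libraries are given here. Between 12 h and 6 h 8 genes differed, among them Mmp3 (2.26), Ptx3 (1.80) and Rims3 (-0.68) as log2 fold changes. Between 24 h and 12 h 28 differed, among them Lyz2 (2.27), Chil3 (2.27), Msr1 (1.5), Camkk1 (-1.24), Nptx1 (-0.69) and Gabbr2 (-0.54). Of these, Lyz2, Msr1, Camkk1, Nptx1 and Gabbr2 each lost their call in 9 of the 12 single-library omissions. Between 24 h and 6 h 649 differed, among them Serpina3n (3.01), Ptx3 (2.95), Mmp3 (2.93), Lyz2 (2.87), Spp1 (2.62), Ccl12 (2.76), Hmox1 (2.18), Car12 (-1.6), Camk2a (-0.99) and Stx1a (-0.92). The tests of transcription switched on or off and of assembled transcripts, the floor test on the genes staying at 0, the neuron share test and both blood cell tests were chosen after their results were seen.

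Groups of 3 against 3 allow 10 splits, too few for a share under 0.05, and in each comparison the real split, 1 of 10, gave the highest count. Real and highest other counts of genes were 616 against 14 at 6 h, 1318 against 10 at 12 h and 742 against 13 at 24 h. Between times they were 23 against 14 (12 h and 6 h), 15 against 13 (24 h and 12 h) and 40 against 9 (24 h and 6 h), each fitted on 6 libraries. For loci they were 763 against 0, 441 against 0 and 261 against 1, and for isoforms 66 against 40, 117 against 29 and 94 against 39.

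At 6 h, 12 h or 24 h against sham, 67 genes were listed at 0 in every library of one group and above 1 FPKM in every library of the other, P2ry12 among them. A fraction floor of 10% as the whole cause is argued against, since only 31.3% of the 67, or 21, made up a share of 0.2 or less where above 0. Assembled transcripts of the same gene were above 0 in every library of the group at 0 in 37.3%, or 25, and movement of FPKM to them may hold for these. In 39 genes none was above 0 in that group, and of these 39 only 7.7%, or 3 (Amy1, Mvp and Opn3), had on their exons an assembled transcript counted elsewhere, which argues against such movement as the cause in most of the 39. Of the 67 only 10.4%, or 7, stayed at 0 and stood alone. For the 32 that stayed at 0 and shared their place with other transcripts (median share 0.18), the fraction floor and transcription switched on or off cannot be told apart, since 59.4%, or 19, made up a share of 0.2 or less and 13, P2ry12 among them, a larger one.

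As lists, synaptic and channel genes were lower and ribosomal protein genes higher at 24 h. A trend with transcript length is argued against as the whole cause, since the synaptic median was -0.63 with the trend removed and -0.72 before, and the ribosomal median 0.37 and 0.48. Scaling is argued against too, since the highest synaptic median under the other scalings was -0.59. A lower share of neurons alone would raise the markers of other cells alike, and astrocyte markers moved against endothelial markers by -0.56 (SE 0.18). The neuron markers themselves would go with it: 0 of 20 lay more than 3 standard errors from the list median, and 3 with assembled transcripts added. A change of transcription within neurons, and a loss of neurons together with a change in another cell type, may remain and were not tested.

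Measured neutrophil and monocyte markers were higher as lists at 24 h, though the minimum for testing favoured markers that rose. Blood left in the vessels as a whole is argued against, since haemoglobin genes moved less than the measured neutrophil markers. Their median log2 fold changes were 0.63, over 4 haemoglobin genes, and 2.66, a gap of -2.03. The combined standard error of 1 typical gene of each kind was 0.57, which is not an error of the gap between medians. Hbb-bs was at 90.5 ± 41.3 FPKM in sham and 157.5 ± 91.5 at 24 h. The size of the gap is also uncertain because the minimum for testing favoured markers that rose. Markers made by cells of the tissue and markers of entering cells cannot be told apart. Of 6 markers less expected from cells of the tissue 5 were higher (S100a8, S100a9, Retnlg, Ifitm6 and Chil3, not Plac8), but 14 of all 18 measured members were, which nearly fixed that count. White cells held in vessels, entry into the tissue and induction in resident cells may each remain.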

How the results depend on the processing

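Of 2745 values of 107 named gene results under the alternatives, 2635 kept direction and side of the threshold, 110 (in 23 results) kept direction but missed it, and 0 reversed. All 107 were called in the main fit, and the text leads with genes also called with assembled transcripts added. That choice partly fixed these counts in advance, so they do not describe genes in general. Of 420 list values 358 kept both, 43 missed the threshold, 14 passed it newly and 5 reversed. Settings chosen after seeing the data were the calls shared by both gene values, the restrictions to values above 0, the lists with assembled transcripts, and for loci the block and omissions. Counts outside 1.5 times the reported ones follow by setting, and except for the stricter filters, the fold minimum and the fits on fewer libraries, the cause was not tested. FPKM as deposited gave 277 (lower at 6 h), 376 (lower at 12 h), 463 (lower at 24 h), 9 (24 h and 12 h) and 1345 (24 h and 6 h), quantile normalization gave 45 (24 h and 12 h), a pseudocount of 0.1 gave 13 (24 h and 12 h), no filter gave 70 (lower at 6 h), 371 (lower at 12 h), 14 (12 h and 6 h) and 201 (called alike at all 3 times), and a mean FPKM of at least 5 gave 418 (higher at 12 h) and 2 (12 h and 6 h). Assembled transcripts added gave 911 (higher at 6 h), 730 (lower at 6 h), 1562 (higher at 12 h), 1624 (lower at 12 h), 1896 (higher at 24 h), 1885 (lower at 24 h), 32 (12 h and 6 h), 262 (24 h and 12 h), 2063 (24 h and 6 h) and 1003 (called alike at all 3 times). A fold of at least 2 gave 199 (higher at 6 h), 25 (lower at 6 h), 309 (higher at 12 h), 82 (lower at 12 h), 376 (higher at 24 h), 111 (lower at 24 h), 14 (24 h and 12 h), 162 (24 h and 6 h) and 147 (called alike at all 3 times). The 2 groups alone gave 462 (higher at 24 h), 280 (lower at 24 h), 23 (12 h and 6 h), 15 (24 h and 12 h) and 40 (24 h and 6 h), no trend 18 (24 h and 12 h), and library weights 675 (higher at 6 h), 425 (lower at 6 h), 7 (24 h and 12 h) and 505 (called alike at all 3 times). Calls shared by both gene values gave 3 (12 h and 6 h) and 18 (24 h and 12 h), and genes above 0 in every library 2 (12 h and 6 h) and 50 (24 h and 12 h). The replicate block gave 94 (lower at 6 h), 5 (24 h and 12 h) and 31 (isoforms at 6 h). The replicate numbers showed no clear pairing of libraries. The 18 same-number pairs had correlations from -0.065 to 0.064, and from -0.085 to 0.115 with assembled transcripts added. For isoforms, a mean of at least 5 gave 15 (isoforms at 6 h), 25 (isoforms at 12 h) and 29 (isoforms at 24 h), logit shares 20 (isoforms at 6 h), 33 (isoforms at 12 h) and 21 (isoforms at 24 h), and genes with all transcripts above 0 4 (isoforms at 6 h), 20 (isoforms at 12 h) and 16 (isoforms at 24 h). For loci, a mean of at least 5 gave 101 (loci higher at 6 h), 0 (loci lower at 6 h), 90 (loci higher at 12 h), 2 (loci lower at 12 h), 67 (loci higher at 24 h) and 0 (loci lower at 24 h), and merging by 0.5 overlap 10 (loci lower at 12 h) and 2 (loci lower at 24 h). With an estimated correlation 13 calls against 43 were made for gene lists and 4 of 15 for markers. In all, 4 lists not called in the main test took the other direction at 6 h: interferon response (adjusted p 0.797 as deposited, 0.744 with assembled transcripts) and, with assembled transcripts, cell cycle (0.853), oxidative phosphorylation (0.845) and choroid plexus markers (0.853). Omitting each library in turn (group and replicate number) gave 167 without 6 h 3 to 426 without 24 h 2 (higher at 6 h), 33 without 6 h 3 to 268 without 24 h 2 (lower at 6 h), 388 without sham 1 to 789 without 24 h 2 (higher at 12 h), 243 without sham 1 to 720 without 24 h 2 (lower at 12 h), 644 without sham 1 to 1054 without 24 h 3 (higher at 24 h), 478 without sham 1 to 948 without 24 h 3 (lower at 24 h), 8 without sham 2 to 15 without 24 h 2 (12 h and 6 h), 7 without sham 1 to 177 without 24 h 3 (24 h and 12 h), 209 without 6 h 3 to 1001 without 24 h 3 (24 h and 6 h), 158 without sham 1 to 371 without 24 h 2 (called alike at all 3 times), 30 without sham 1 to 51 without 12 h 3 (isoforms at 6 h), 55 without sham 1 to 107 without 12 h 3 (isoforms at 12 h), 36 without sham 2 to 76 without 6 h 1 (isoforms at 24 h), 458 without sham 2 to 667 without 12 h 2 (loci higher at 6 h), 8 without sham 1 to 22 without 12 h 1 (loci lower at 6 h), 226 without sham 2 to 485 without 12 h 3 (loci higher at 12 h), 5 without sham 1 to 23 without 6 h 2 (loci lower at 12 h), 96 without sham 2 to 185 without 12 h 1 (loci higher at 24 h), 0 without sham 1 to 3 without 6 h 2 (loci lower at 24 h). A library whose omission leaves a group with 2 is fitted with the spread shared over groups. The libraries whose omission moved a count by more than 1.5 times are named with each count in the results. Read totals are not given, so the effect of depth on low genes could not be computed.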

Other observations

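The loci outside the reference that were higher at 6 h had a position that is given here as values. Of the 613, 574 were not assembled in any sham library and so were given 0 there, and the median FPKM of the 613 was 0 in sham, 3.95 at 6 h, 2.25 at 12 h and 0.899 at 24 h. They lay within 10 kb downstream of a gene on the same strand in 18.9% against 40.1% of loci not called (Fisher exact p 1.22e-24). Of the 59 measured upstream genes 2, or 3.39%, were called higher, a share similar to that over all genes tested (361 of 12597). The 613 loci lay antisense to a gene in 33.9% against 20.1%, and within 100 kb of a risen gene in 11.6% against 8.07% (Fisher exact p 0.00695). The strand of loci with 1 exon rests on a strand setting that is not given, so the shares by strand are uncertain. Loci are not independent replicates, and these comparisons were made after the loci were seen.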
